A study of Homo sapiens with 6 samples.

How the data were processed

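MYC chromatin immunoprecipitation sequencing (ChIP-seq) was carried out in MIAPaCa2, a human pancreatic ductal adenocarcinoma cell line. Per the labels, the cells were kept without serum for 48 hours and then given, for 3 hours, either fresh serum-free DMEM or conditioned medium (CM) from cancer-associated fibroblasts. Of the 6 samples, 4 are immunoprecipitated libraries, 2 per condition, and the other 2 are inputs, 1 per condition. The inputs were not analysed here. Nothing in the labels says whether the 2 libraries of a condition came from separate cultures, so differences between them measure the spread between libraries, which may be technical.

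Each immunoprecipitated library has its own deposited peak list, with a chromosome, a start, an end, a peak name and a whole-number score per peak. The score is the authors' own value for each peak, of at least 13 in all 4 lists. In the output of MACS2 this column usually holds 10 times the −log10 q-value, which the files do not state. The score was used only to rank or filter peaks within 1 list. Per the submitters' processing notes, the tools were Trim Galore 0.4.3, Bowtie2 2.3.4, SAMtools 1.3.1, Picard 2.9.0 and MACS2 2.1.1.20160309 with the genome build GRCh38. Their settings, and which input served as the control of which list, are not given in the sources used here. The authors also deposited common peak lists for CM, for DMEM and for all libraries. In the lists for CM and DMEM, each interval spans overlapping peaks of both libraries and carries their mean score, which was checked on every interval. The files hold no read counts, so sequencing depth is unknown. A library of lower depth or lower immunoprecipitation yield gives fewer peaks at the same threshold, and no scaling between the libraries was possible.

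Genes were taken from the RefSeq annotation of GRCh38.p14 as a table of positions without strand. All peaks lay on chromosomes 1 to 22, X and Y, and 20033 protein-coding genes on these chromosomes formed the background. The plan was to count peaks within 1000 bp of transcript starts. Since the table used here gives no strand and no transcripts, a gene was called bound when a peak lay within 1000 bp of either of its outermost annotated ends. Starts inside a gene are missed by this rule, and a peak between neighbouring genes counts for each of them. The peaks by which a gene is bound in different libraries need not overlap. Among 14342 genes longer than 10000 bp, peaks at both ends were found in 224 and 178 genes of the CM libraries and in 40 and 87 genes of the DMEM libraries. If both ends were used independently, these counts correspond to a peak at the less used end in 1.67% to 3.38% of genes. No genome sequence was used here. The planned search for the CACGTG motif and the background of CpG-rich promoters were therefore not run, nor was a ranking by fold enrichment.

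A call for a condition required both of its libraries. CM-only means bound in both CM libraries and in neither DMEM library, DMEM-only the opposite, and shared means bound in all 4. Peaks were compared by overlaps of at least 1 bp, beside overlaps after 100 random circular shifts along each chromosome, and were merged across libraries to count intervals by condition. Peak numbers were compared by an exact two-sided permutation test over all 6 relabellings. Fixed gene lists were tested by two-sided Fisher's exact tests against all protein-coding genes, separately for CM and DMEM. For the difference between the conditions, CM-only was set against shared among the genes bound in CM, for lists with at least 5 such members. The p-values were adjusted by the Benjamini-Hochberg method over the lists of each test, with a threshold of 0.05. Genes are not independent replicates, so these p-values describe these libraries. Scores of shared and CM-only intervals were compared within each CM list by a permutation test with 100000 resamples.

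The 23 lists, holding 663 different genes, covered ribosome biogenesis, cytosolic ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, nucleotide and one-carbon synthesis, glycolysis and lactate transport, amino acid transport and synthesis, the mitochondrial ribosome with import and chaperones, DNA replication, cell cycle regulators, RNA splicing, cytosolic chaperones, the proteasome, the MYC network, immediate-early and ERK feedback genes, FGF ligands and receptors, cytokines and growth factors of tumour cells, cholesterol and fatty acid synthesis, lysosome and autophagy, ductal and epithelial markers, acinar and islet markers, fibroblast markers, blood and immune markers, and liver and neuronal genes. The named genes are the 12 CM-only genes and the 8 genes bound in all 4 libraries with the highest mean score percentile, up to 5 DMEM-only genes, up to 4 leading members of each list past the threshold, and all members of the MYC network bound in CM. The groups, tests, lists, naming rule and the alternative settings, apart from those said to be added, were set before the data were examined. Genes named outside this rule are said to have been chosen after their values were seen, except list members given as examples of a count.

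The alternatives were a minimum score of 50, lists limited to the 4657 peaks with the highest scores (the length of the shortest list), each library left out in turn, the authors' common lists, windows of 500 and 2500 bp, an overlap of at least 0.5 of the shorter peak, and a Cochran-Mantel-Haenszel test with the replicate number as a block. Added after the data had been seen were a background of genes bound in any library, counting by peak midpoint, counting genes bound in 1 DMEM library with CM-only, and requiring of CM-only genes that no DMEM peak overlaps their CM peaks. The overlap and merging steps were checked against bedtools 2.31.1, with 0 differences in 12 list pairs and 16235 merged intervals. On simulated lists of 30 genes for the CM test, 99% of 200 changed lists, with odds 6 times higher, and 0.5% of 200 unchanged lists were called. Smaller effects were not simulated for this test. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.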

Results

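MYC binding was mapped by ChIP-seq in serum-starved MIAPaCa2 cells after 3 hours in conditioned medium from cancer-associated fibroblasts (CM) or in fresh serum-free DMEM. MYC is a transcription factor that binds DNA together with MAX. Peak lists of 2 libraries per condition were compared, and the question was which genes carried MYC in the starved cells and which carried it after fibroblast medium. The CM lists held 15304 and 12797 peaks and the DMEM lists 4657 and 7652 peaks. Read depth is unknown for all 4 libraries, so every count below is a count at the authors' peak threshold and not a level of binding.

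In starved cells given DMEM, MYC peaks lay at the genes of the protein synthesis machinery. Of 40 cytosolic ribosomal protein genes, 37 were bound in both DMEM libraries, and of 40 ribosome biogenesis genes, 31 were bound. In CM the same lists had 38 and 37 bound genes. The highest-ranked peaks in all 4 libraries included that at NCL (nucleolin, a nucleolar protein of ribosome assembly), on chromosome 2 with the gene at 231453531 to 231464484. After CM, peaks were called at many more genes, and 2198 genes were bound in CM alone, among them FOS, JUN, PCNA, TFEB and TGFB2, examples chosen after their values were seen.

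Protein-coding genes with a peak at an end numbered 8803 and 8197 in the CM libraries, a mean of 8500 ± 429 (SD, n = 2). The DMEM libraries had 3367 and 5620, a mean of 4493.5 ± 1593 (SD, n = 2). CM had 2.34 times as many peaks as DMEM by geometric means, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. CM peaks were also wider, with median widths of 691 and 593 bp against 430 and 431.5 bp, and covered 14.6 and 9.90 Mb against 2.85 and 4.24 Mb. Lower shares of the CM peaks lay at ends of protein-coding genes, 61.9% and 66.1% against 72.9% and 71.8% in DMEM.

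**Figure D1:**
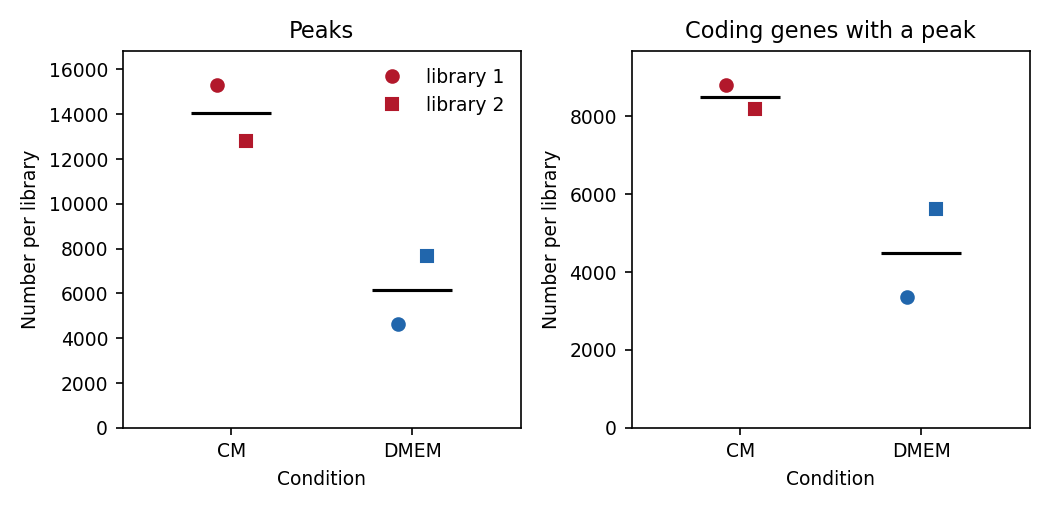
Number of peaks (left) and of protein-coding genes with a peak within 1000 bp of an end (right) in each library, with CM in red and DMEM in blue. Circles are library 1, squares library 2 and horizontal lines the means, and both CM libraries lie above both DMEM libraries.

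Nearly all genes bound in DMEM were bound in CM as well. Of 3184 genes bound in both DMEM libraries, 3178 were bound in all 4 libraries, where independent lists would share 1245 (odds ratio 1387). Of the 7835 genes bound in both CM libraries, 3178 (40.6%) were shared, 2459 (31.4%) were bound in 1 DMEM library and 2198 (28.1%) in none. No gene was DMEM-only, against 6 without CM library 1, 31 without DMEM library 1 and 1 without DMEM library 2. The number of CM-only genes rests on DMEM library 2: it was 4488 without that library and 2367 without DMEM library 1, while DMEM library 2 alone gave 5620 bound genes in place of 3184, and 5468 in place of 3178 shared genes. When each list was limited to its 4657 highest-scoring peaks, 387 genes were CM-only and 74 were DMEM-only.

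Single peaks showed the same nesting. CM peaks overlapped 98.0% and 93.9% of the peaks of DMEM library 1, for CM libraries 1 and 2, and 96.9% and 93.7% of those of DMEM library 2. In the other direction, DMEM peaks overlapped 23.9% to 50.4% of the peaks of a CM library. Random shifts of the other list gave mean overlaps of 0.967% and 0.704% for DMEM library 1 and 0.909% and 0.693% for DMEM library 2. Within conditions, the longer list overlapped 89.2% of the peaks of the shorter in CM and 81.0% in DMEM, and the shorter overlapped 68.5% and 46.7% of the peaks of the longer. Merging gave 16235 intervals, of which 3343 were shared, 3547 CM-only, 2992 in both CM and 1 DMEM library, and 3 DMEM-only. CM-only intervals numbered 6011 and 8573 without CM library 1 or 2 and 6335 without DMEM library 2, and shared ones 6117 without DMEM library 1. DMEM-only intervals numbered 25 and 8 without CM library 1 or 2, and 129 and 78 without DMEM library 1 or 2. Of the CM-only intervals 61.9% lay at a gene end, against 79.5% of the shared ones, a difference of -17.6 percentage points (Fisher's exact test, p = 2.56e-58). It was -27.4 points without CM library 2 and -8.22 points in lists of equal length.

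The genes with the highest scores in all 4 libraries were PCBP1 (an RNA-binding protein), ASPRV1, MGME1, SNX5, NCL, ZNF131, EIF3B (a subunit of the translation initiation factor eIF3) and LOC124904958. Their peaks averaged the 99.8 to 99.9 percentile of the 4 lists. PCBP1 and ASPRV1 share a peak on chromosome 2, from 70085535 to 70089565 in CM library 1, and MGME1 and SNX5 share another on chromosome 20, from 17966868 to 17970329. The peak of LOC124904958 also lies at the end of SNHG17, a noncoding host gene of small nucleolar RNAs.

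Genes of ribosome production, translation and splicing were over-represented in both conditions, against all protein-coding genes. Since the background of CpG-rich promoters was not run, these tests do not tell a preference for the lists from one for such promoters. Values for lists are odds ratios and p-values of Fisher's exact tests after Benjamini-Hochberg adjustment, for CM and then for DMEM. Of 40 ribosome biogenesis genes 37 and 31 were bound (odds ratios 19.3 and 18.4, Fisher p = 2.12e-11 and 1.08e-16), and NCL, NOLC1, WDR43 and NPM1, at CM percentiles of 99.8 to 99.9, were bound in all 4 libraries. Of 40 cytosolic ribosomal protein genes 38 and 37 were bound (odds ratios 29.7 and 66.0, Fisher p = 2.10e-12 and 3.22e-25), among them RPL5, RPL13 and RPS19. Of 37 translation factors and aminoacyl-tRNA synthetases 33 and 27 were bound (odds ratios 12.9 and 14.4, Fisher p = 1.91e-09 and 1.27e-13), among them EIF3B, EIF4G1, EIF5A and IARS1. Of 32 RNA splicing genes 31 and 24 were bound (odds ratios 48.5 and 16.0, Fisher p = 3.38e-11 and 1.02e-12), such as SF3B3, SRSF6, U2AF2 and HNRNPA1. Of 24 cytosolic chaperone genes 20 and 17 were bound (odds ratios 7.80 and 12.9, Fisher p = 5.22e-05 and 1.31e-08), led by the chaperonin subunits CCT3, CCT5, CCT4 and CCT6A.

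Metabolic genes were over-represented in both conditions too. Of 30 nucleotide and one-carbon synthesis genes 28 were bound in CM and 17 in DMEM (odds ratios 21.9 and 6.95, Fisher p = 2.90e-09 and 1.08e-06), led by NME1, ATIC, MTHFD1L and MTHFD2. Amino acid transport and synthesis had 15 and 14 of 20 genes (odds ratios 4.68 and 12.4, Fisher p = 0.00291 and 3.65e-07), including the serine synthesis enzyme PSPH and the transporter genes SLC3A2, SLC7A1 and SLC7A5. The PSPH peak is the same as that of the chaperonin gene CCT6A, and the SLC3A2 peak also lies at the end of SNHG1. Glycolysis and lactate transport had 15 and 10 of 23 genes (odds ratios 2.92 and 4.08, Fisher p = 0.0191 and 0.00361), with ENO1, HK2, LDHA and GAPDH at percentiles of 93.3 to 99.8 in CM. Cholesterol and fatty acid synthesis had 17 and 11 of 24 genes (odds ratios 3.79 and 4.49, Fisher p = 0.00340 and 0.00136), led by FASN, DHCR7, SREBF1 and LSS. Genes of the mitochondrial ribosome, import and chaperones had 31 and 19 of 35 bound (odds ratios 12.1 and 6.32, Fisher p = 6.67e-09 and 6.33e-07), led by MRPL3, MRPL15, HSPA9 and HSPD1. With genes bound in any library as the background, glycolysis (Fisher p = 0.0770) and cholesterol synthesis (0.110) did not pass in DMEM. Cholesterol synthesis did not pass in DMEM with a minimum score of 50 either (Fisher p = 0.228).

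**Figure D2:**
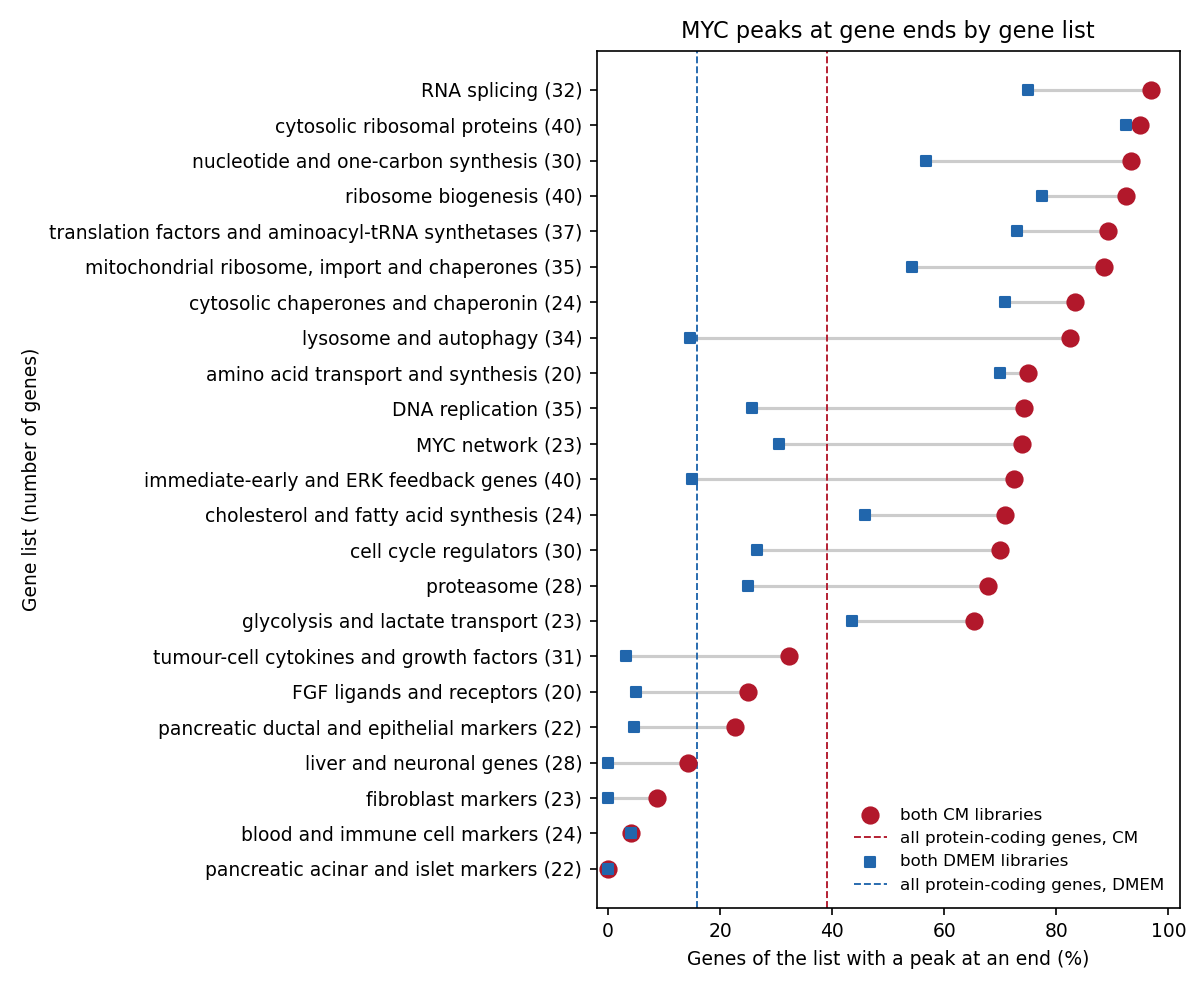
Share of the genes of each fixed list with a peak at an end in both CM libraries (red circles) and in both DMEM libraries (blue squares), in percent, with the number of genes in parentheses. Dashed lines give all protein-coding genes, 39.1% in CM and 15.9% in DMEM, and lysosome and autophagy genes lie at 82.4% and 14.7%.

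DNA replication, cell cycle, proteasome, immediate-early and lysosome genes passed the threshold in CM and missed it in DMEM. Passing in CM alone is not a tested difference between the conditions. The test of CM-only against shared genes, given below, called the lysosome genes alone among these lists. That call was lost whichever library was left out. Of 35 DNA replication genes 26 and 9 were bound (odds ratios 4.51 and 1.83, Fisher p = 6.89e-05 and 0.205). POLD2, MCM7 and MCM4 were bound in all 4 libraries, CDC7 in 1 DMEM library, and PCNA, the replication clamp, was CM-only. Of 30 cell cycle regulators 21 and 8 were bound (odds ratios 3.64 and 1.93, Fisher p = 0.00170 and 0.185), with CKS2, E2F3, CKS1B and CDKN2C bound in all 4 and CDK6 and CCNE2 CM-only. In both CM libraries and DMEM library 1, the highest-scoring CKS2 peak lay at the high-coordinate end of the gene. That of CM library 1 also lay at the end of SECISBP2, and that of DMEM library 2 at the low-coordinate end of CKS2. The CDKN2C peak of DMEM library 1 was at percentile 1.2 of its list. Of 28 proteasome genes, led by PSMA2, PSMA3, PSMC5 and PSMD7, 19 and 7 were bound (odds ratios 3.29 and 1.77, Fisher p = 0.00372 and 0.235). Immediate-early and ERK feedback genes, an early transcriptional response to growth factors, had 29 and 6 of 40 bound (odds ratios 4.12 and 0.934, Fisher p = 5.95e-05 and 1.0). DUSP2, FOSL2 and FOSL1 were bound in all 4 libraries, IER2 in 1 DMEM library, and FOS, JUN and MCL1 in CM alone. The FOSL1 peak of CM library 1 lay outside that gene and also at the end of its neighbour CCDC85B. Lysosome and autophagy genes had 28 and 5 of 34 bound (odds ratios 7.29 and 0.912, Fisher p = 1.12e-06 and 1.0), with ATG9A, ATP6V1A and GAA bound in all 4. Another 11, such as MAP1LC3B, were bound in both CM libraries and in 1 DMEM library. The ATG9A peak of CM library 1 also lay at the end of ABCB6. At ATP6V1A, the peak of DMEM library 1 was at percentile 8.3 of its list. The highest-scoring GAA peaks of DMEM library 1 and DMEM library 2 did not overlap.

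The missing calls in DMEM rest on DMEM library 1 for all of these but the lysosome genes. Lysosome genes did not pass in DMEM library 2 alone either, although 15 of 34 were bound there, against 6 in DMEM library 1. Of all 20033 protein-coding genes, 5620 and 3367 were bound in these 2 libraries. In DMEM library 2 alone, DNA replication (odds ratio 3.05, Fisher p = 0.00254), cell cycle regulators (2.57, 0.0174), the proteasome (2.96, 0.00828) and immediate-early genes (2.32, 0.0174) passed. With the CM lists shortened to their 4657 highest-scoring peaks, DNA replication (14 of 35, odds ratio 3.04, Fisher p = 0.00598) and cell cycle regulators (12 of 30, odds ratio 3.04, Fisher p = 0.0125) still passed. Proteasome, immediate-early and lysosome genes did not (odds ratios 1.24, 1.52 and 0.784).

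MYC's own network was over-represented in CM, with 17 of 23 genes bound (odds ratio 4.42, adjusted Fisher p = 0.00164), against 7 in DMEM (odds ratio 2.32, adjusted Fisher p = 0.121). In DMEM library 2 alone it passed as well (odds ratio 4.82, adjusted Fisher p = 5.76e-04). MAX, the partner of MYC, and the MAX-binding repressors MXD1, MXD3, MNT and MGA were bound in all 4 libraries, as were RUVBL1 and WDR5. ZBTB17 and PIM1 were CM-only. The highest-scoring ZBTB17 peaks of CM library 1 and CM library 2 did not overlap, and lay at percentiles of 17.9 and 41.7 of these lists. KAT5, MLX, RUVBL2, AURKA, FBXW7, MLXIPL, TRRAP and MYC itself had a peak in 1 DMEM library. The MYC gene lies on chromosome 8 at 127735434 to 127742951. Its highest-scoring peak at a gene end spanned 127734796 to 127735984 in CM library 1 and 127734865 to 127736179 in CM library 2, at percentiles of 65.0 and 50.1 of these lists. DMEM library 2 had a peak there at 127735735 to 127736139, at percentile 3.8 of its list, and DMEM library 1 had none.

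**Figure D3:**
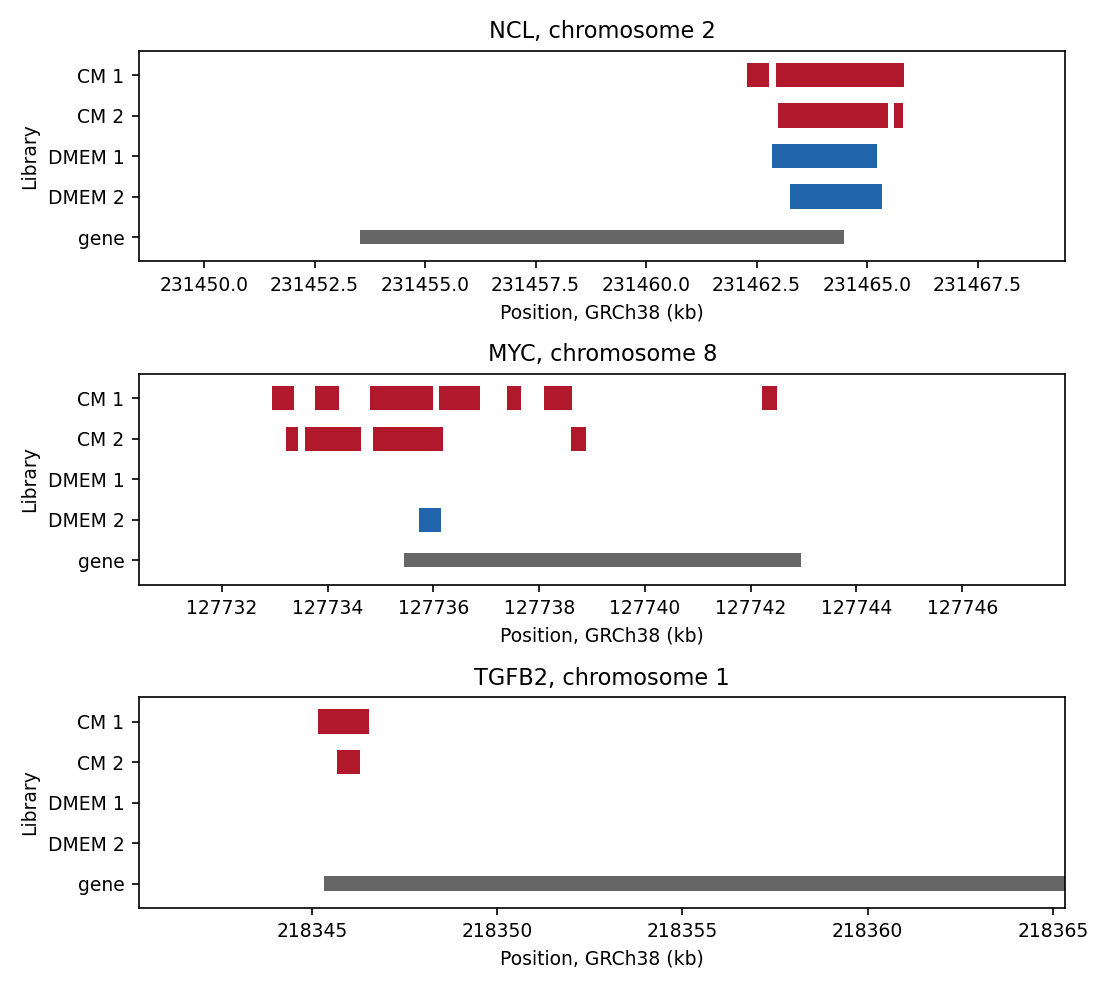
Peaks of each library (1 line each; CM in red, DMEM in blue) around NCL, MYC and the low-coordinate part of TGFB2, with the position on GRCh38 in kb on the horizontal axis and the gene as a grey bar. NCL has peaks in all 4 libraries, MYC in both CM libraries and DMEM library 2, and TGFB2 in the CM libraries alone.

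Acinar and islet, fibroblast, blood and immune, and liver and neuronal genes were rarely bound. The FGF, ductal and cytokine lists, given after them, passed the threshold in neither condition. Of 22 acinar and islet markers none was bound in any library (Fisher p = 5.95e-05 for under-representation in CM and 0.0702 in DMEM). Of 23 fibroblast markers 2 were bound in CM, VIM and S100A4, and 0 in both DMEM libraries (odds ratio 0.148 in CM, Fisher p = 0.00299 and 0.0702). VIM and S100A4 each had a peak in DMEM library 2 as well. The highest-scoring S100A4 peaks of CM library 1 and CM library 2 did not overlap, and that of CM library 1 also lay at the end of S100A5. Of 24 blood and immune markers CD8A alone was bound in both libraries of a condition, in CM and in DMEM (odds ratios 0.0676 and 0.230, Fisher p = 3.54e-04 and 0.205). Liver and neuronal genes had 4 of 28 bound in CM and 0 in DMEM (odds ratio 0.259 in CM, Fisher p = 0.00742 and 0.0340). These 4 were SYP, TUBB3, TF and GRIN1, and the peak of each also lay at the end of a neighbour, PRICKLE3, MC1R, TOPBP1 and LRRC26 in that order. FGF ligands and receptors had 5 and 1 of 20 bound (odds ratios 0.519 and 0.278, Fisher p = 0.265 and 0.385), with FGFR1, FRS3, GAB1 and GRB2 CM-only. Ductal and epithelial markers had 5 and 1 of 22 bound (odds ratios 0.458 and 0.252, Fisher p = 0.143 and 0.274), where KRT8, KRT18 and KRT19 were CM-only and MUC1 was bound in all 4. Cytokines and growth factors had 10 of 31 bound in CM and 1, VEGFA, in DMEM (odds ratios 0.741 and 0.176, Fisher p = 0.468 and 0.0823). In DMEM library 2 alone the acinar (Fisher p = 0.00260), fibroblast (0.0436), blood (0.0436) and FGF (0.0284) lists were under-represented, as were fibroblast markers (0.0492) in DMEM library 1 alone. Liver and neuronal genes were not under-represented in DMEM library 1 alone (odds ratio 0.183, Fisher p = 0.112). Of the 4 lists under-represented in CM, acinar and islet markers alone passed in lists of equal length (Fisher p = 0.0376), against 0.136 for fibroblast and blood markers and 0.0726 for liver and neuronal genes.

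The difference between the conditions was tested by setting CM-only against shared genes, for 18 lists. Cytokine and growth factor genes were more often CM-only than other genes, 7 of the 8 that were CM-only or shared (87.5%, against 40.8% of other such genes; odds ratio 10.2, adjusted Fisher p = 0.0220). The 7 were CSF1, CXCL1, EREG, PDGFA, PDGFB, TGFB1 and TGFB2, while CXCL5 and HBEGF had a peak in 1 DMEM library. Lysosome and autophagy genes were also more often CM-only, 12 of 17 or 70.6% (odds ratio 3.48, adjusted Fisher p = 0.0413), including TFEB and TFE3, transcription factors of lysosomal genes, and LAMP2, CTSB, CTSD and BECN1. In lists of equal length both had fewer than 5 CM-only and shared members and were not tested. Neither call held with a minimum score of 50 or with genes bound in 1 DMEM library counted with CM-only. The lysosome call was lost with windows of 500 or 2500 bp and by peak midpoint, and the cytokine call with the authors' common lists. The cytokine call did not hold without CM library 1 (adjusted Fisher p = 0.0512) or DMEM library 2 (0.0975). The lysosome call was lost whichever library was left out: without CM library 1 or 2 its adjusted Fisher p was 0.0772 or 0.143, and without DMEM library 1 or 2 it was 0.114 or 0.0527.

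Ribosomal, translation and splicing genes were among 8 lists that were less often CM-only than other genes, with genes bound in 1 DMEM library left out of the shares. By adjusted Fisher p, these were cytosolic ribosomal proteins (0% of 37, 8.02e-08), ribosome biogenesis (3.12% of 32, WDR74 alone, 1.42e-05), cytosolic chaperones (0% of 17, 0.00123) and RNA splicing (7.69% of 26, SF3B1 and SRSF11, 0.00178). The others, by adjusted Fisher p, were translation factors and aminoacyl-tRNA synthetases (12.9% of 31, 0.00499), amino acid transport and synthesis (6.67% of 15, CHAC1 alone, 0.0199), mitochondrial genes (13.6% of 22, 0.0217) and nucleotide synthesis (15% of 20, 0.0413). Without DMEM library 1 the last 4 were no longer called (adjusted Fisher p = 0.0700, 0.0946, 0.0946 and 0.153), nor was nucleotide synthesis without DMEM library 2 (0.0703). No call was made, by adjusted Fisher p, for glycolysis (1 of 11, 0.0546), immediate-early genes (9 of 15, 0.240), FGF genes (4 of 5, 0.240), cholesterol synthesis (3 of 14, 0.240), the MYC network (2 of 9, 0.390), the proteasome (3 of 10, 0.609), DNA replication (7 of 16, 0.852) or cell cycle regulators (5 of 13, 1.0). In lists of equal length none of the 8 calls held. Nucleotide synthesis was also lost with windows of 500 bp, with the authors' common lists and with genes bound in 1 DMEM library counted with CM-only. Mitochondrial genes were lost under the last 2 of these, and amino acid genes with windows of 500 bp.

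CM-only peaks were the lower-scoring part of the CM lists. In CM library 1 a shared interval had a higher score than a CM-only one with a probability of 0.955, and in CM library 2 of 0.945 (permutation tests, p = 1e-05 each, the smallest these tests can give). Median scores were 264 against 74 and 228 against 62. Of the 10% of peaks with the highest scores in CM library 1, 95.8% overlapped a peak of DMEM library 1 and 99.6% a peak of DMEM library 2. Of the lowest 10%, 6.08% overlapped a peak of DMEM library 2.

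**Figure D4:**
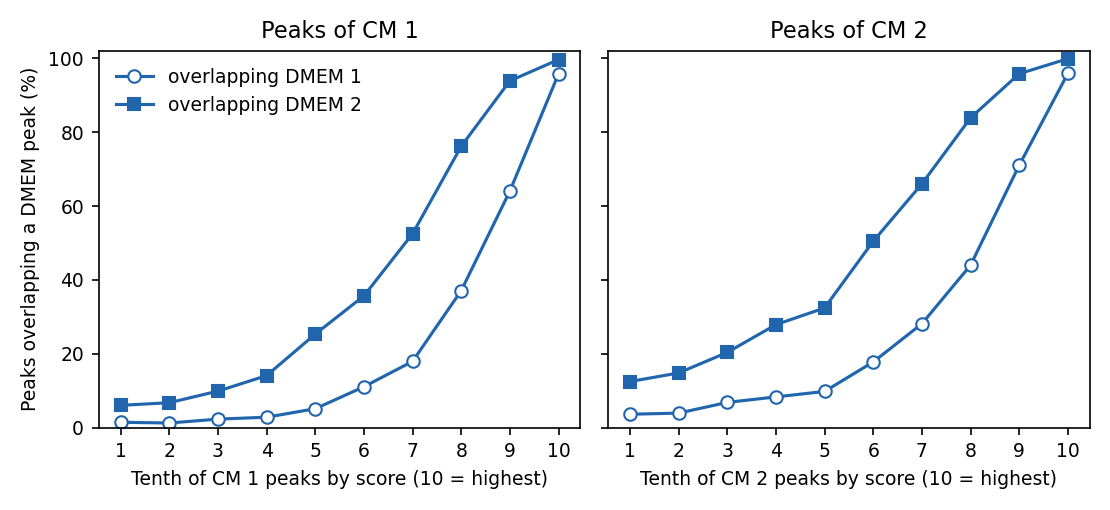
Share of the peaks of CM library 1 (left) and CM library 2 (right) that overlap a peak of DMEM library 1 (open circles) or DMEM library 2 (filled squares), in percent, in 10 parts of equal size from the lowest (1) to the highest (10) scores. For CM library 2 the shares rise from 3.67% and 12.5% in the lowest part to 95.9% and 99.8% in the highest.

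The 12 CM-only genes with the highest scores in CM were ARL6IP1, AP1S1, LRRC8E, CHD9NB, NADK, CAMKK2, ZNF581, SYP, JADE1, CABLES2, GMPS and ALKBH4, at percentiles of 89.0 to 96.3. At 11 of these 12, all but ALKBH4, a DMEM peak overlapped the CM peak and ended outside the window at the gene's end. For example, the peak of ARL6IP1 also lies at the end of RPS15A, and that of CABLES2 at the end of RPS21. The same held for 107 of the 2198 CM-only genes, among them TGFB1. Among the remaining 2091 genes, a set chosen after the values were seen, the 12 ranked highest were ALKBH4 and LRWD1 (1 shared peak), STK10, CHCHD3, WAC, ZNF775, CCNE2 and NDUFAF6 (1 shared peak), PRPS2, CYP20A1, SFXN1 and NF1, at percentiles of 80.7 to 89.0. PRPS2 makes the ribose donor of nucleotide synthesis, CCNE2 is a cyclin of S phase entry, and NF1 is a negative regulator of RAS. With these 2091 genes in place of all CM-only genes, cytokine genes (adjusted p = 0.0324) and lysosome genes (adjusted p = 0.0270) remained more often CM-only by Fisher's exact test.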

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

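The alternatives added after the data had been seen are the background of genes bound in any library, the peak midpoint, genes bound in 1 DMEM library counted with CM-only, and CM-only genes without a DMEM peak under their CM peak; the tests of these were chosen after the result was seen. Of the values that answer a comparison, 110 stayed within 1.5 times or the spread of the value reported and 50 moved. Of the values for single lists, 551 kept their side of the threshold, 53 lost and 20 gained a call, and 7 reversed. The 551 include values without a call whose direction changed, such as immediate-early genes in DMEM (odds ratio 0.934, and 1.05 without DMEM library 2). The cause was not tested for any change below except those of the equal-length lists and the left-out libraries, where fewer peaks or a single library per condition enter by construction. In lists of equal length there were 3609 genes bound in CM, 387 CM-only and 74 DMEM-only genes, and 399 CM-only and 90 DMEM-only peaks; 80.0% of DMEM peaks overlapped CM peaks (95.6% in full lists) and 68.7% of CM peaks overlapped DMEM peaks (36.3%). In these lists 1 list was under-represented in CM and 0 in DMEM, 0 of the 14 lists with enough members were more often and 0 less often CM-only (cytokine, lysosome, proteasome and FGF genes were too few to test), and the odds ratios of lysosome genes in CM (0.784) and, for CM-only against shared, of nucleotide synthesis (1.19) and mitochondrial genes (1.06) changed sides. The authors' common lists, which do not exclude peaks found in 1 library of the other condition, gave 4738 CM-only and 5 DMEM-only genes, 6720 CM-only and 22 DMEM-only peaks, 1 list more often CM-only and 6 less often. A minimum score of 50 gave 1 DMEM-only gene, 9 lists over-represented and 0 under-represented in DMEM and 0 more often CM-only. With an overlap of 0.5 of the shorter peak there were 6 DMEM-only peaks, and 92.3% of DMEM peaks overlapped CM peaks. Windows of 2500 bp gave 3 lists under-represented in DMEM and 1 more often CM-only, and windows of 500 bp gave 1 more often and 6 less often CM-only. Against genes bound in any library, 2 lists were over-represented and 0 under-represented in CM, 8 were over-represented (10 with the background of all protein-coding genes) and 0 under-represented in DMEM, and DNA replication (0.904), proteasome (0.660) and MYC network (0.985) had odds ratios below 1 in CM. Most genes of that background are bound in CM by construction, lists with all such members bound can still miss the threshold, and acinar and islet markers have no member in it, so it says nothing about the lists in CM. The peak midpoint gave 9 DMEM-only genes and 1 list more often CM-only, and with genes bound in 1 DMEM library counted with CM-only there were 0 such lists and 6 less often CM-only. With CM-only genes without a DMEM peak under their CM peak, 2091 genes, 2 lists more often and 8 less often CM-only were found. Leaving out 1 DMEM library gave 3367 to 5620 genes bound in DMEM and odds ratios of 1.05 to 2.32 there for immediate-early genes. Leaving out any 1 of the 4 libraries gave ranges of 3178 to 5468 genes bound in all libraries, 2367 to 4488 CM-only and 0 to 31 DMEM-only genes, 3771 to 8573 CM-only, 8 to 129 DMEM-only and 3341 to 6117 shared peaks. In the same ranges 1 to 5 lists were under-represented in DMEM, and 0 to 1 more often and 4 to 8 less often CM-only.

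With the replicate number as a replicate block, 3 lists were more often bound in CM without DMEM, FGF genes being added, and 10 were less often so. Here a gene counted when bound in a CM library and not in the DMEM library of that number, which differs from CM-only elsewhere. The same gene can enter both blocks, which lowers the p-values without adding genes, so the added calls are no further support. The numbers 1 and 2 are shared by name only: differences between libraries 1 and 2 in CM and in DMEM correlated across 3178 genes with r = 0.07, and genes are not independent replicates. Not run were the motif search, the background of CpG-rich promoters and the ranking by fold enrichment. Depth is unknown, so a peak missing in DMEM was not detectable at the authors' threshold and is not shown to be absent.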

Other observations

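The tests of snoRNA host genes, of groups of genes with shared symbols and of peak width by midpoint were chosen after the result was seen, while those of detection limit and peak score were chosen before their own results but after the peak lists had been looked at. Noncoding host genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, had MYC peaks in both conditions. Of 30 such genes (the SNHG genes and GAS5), 23 were bound in CM, 76.7% against 11.6% of other lncRNA genes (Fisher's exact test, p = 2.76e-16), and 21 in DMEM, 70.0% against 4.63% (Fisher's exact test, p = 1.16e-21). SNHG22 was CM-only. Of 7 hosts without an end of a protein-coding gene nearby, SNHG5, SNHG11, SNHG15 and SNHG26 were bound in all 4 libraries. The peak with the highest score in CM library 1 lay at SNHG15, on chromosome 7 at 44984295 to 44988125 after merging. Another of the highest, on chromosome 7 at 4640515 to 4643609, lay at no gene end, 40234 bp from the nearest end of a protein-coding gene, FOXK1. Of 429 tRNA genes, 116 (27.0%) were bound in CM and 45 (10.5%) in DMEM, lower shares than the 39.1% and 15.9% of protein-coding genes. Of the 354 without an end of a protein-coding gene nearby, 67 (18.9%) were bound in CM and 23 in DMEM. A peak near several tRNA genes counts for each of them.

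Among 24 groups of genes formed by shared symbols, adjusted together by the Benjamini-Hochberg method, 9 were over-represented in CM by adjusted Fisher p. These were RNA helicases (43 of 54, 8.62e-09), nucleoporins (20 of 23, 1.22e-05), RNA polymerase subunits (25 of 33, 7.61e-05), NADH dehydrogenase subunits (26 of 37, 3.88e-04), vacuolar sorting genes (24 of 35, 0.00170), ubiquitin-conjugating enzymes (23 of 36, 0.00698), ATP synthase subunits (14 of 20, 0.0192), V-ATPase subunits (14 of 22, 0.0487) and genes with MAPK, MAP2K or MAP3K symbols (24 of 43, 0.0487), which include some that are not kinases, such as MAPK8IP3. Olfactory receptors (0 of 392, adjusted Fisher p = 9.29e-85), protocadherins (1 of 66, 5.11e-12), interleukins and their receptors (8 of 85, 7.93e-09), keratins (4 of 55, 9.02e-07) and HOX genes (4 of 40, 1.88e-04) were under-represented. The MAPK group was more often CM-only (12 of 15, adjusted Fisher p = 0.0491), with MAPK14, MAP2K1 and MAPK7 among them, and RNA helicases less often (5 of 31, adjusted Fisher p = 0.0491). Neither departed from draws matched on CM score, which gave means of 11.7 (central 95% 9 to 13) and 6.11 (4 to 8) CM-only genes.

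Fewer genes and peaks were called in DMEM than in CM. A detection limit would mean that the same sites rank first in every library and fewer pass the threshold in DMEM. Equal-length lists overlapped by 74.4% on average between conditions (70.8% to 76.1%), against 65.9% for the DMEM pair and 80.4% for the CM pair. The rule set for a fit, any between-condition overlap reaching the lower within-condition one, was met. The low overlap of the DMEM pair made this easy, and all between-condition values lay below the CM pair. Shares also differed by direction: CM library 1 overlapped 84.4% of DMEM library 1 peaks, and the reverse was 65.0%. The comparison therefore cannot decide whether the same sites rank first. Wider peaks in CM as the whole cause are argued against, since 97.3% of the number of CM-only genes, 2139, was found when genes were counted by peak midpoint. A detection limit may come from lower depth or immunoprecipitation yield in the DMEM libraries, or from less MYC on the same sites in starved cells. No read depth or spike-in was used here, so both stay open, the biological one as untested.

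The CM-only shares of the lists may follow from peak score alone. In the 8 lists less often CM-only, 14 of 200 genes were CM-only, where draws matched on CM score gave a mean of 14.7 and a central 95% of 11 to 19. In the 2 lists more often CM-only, cytokines and lysosome genes, it was 19 of 25, where matched draws gave a mean of 17.6 and a central 95% of 15 to 20. In simulations these draws found a list effect in 66% of 100 single lists, each made less often CM-only by a fixed amount. A weaker effect specific to a list would often be missed. Neither lists made more often CM-only nor a pool of 200 genes was simulated, so 66% is not the power of the comparisons above. Whether lysosomal and cytokine genes such as TFEB and TGFB2 gain MYC selectively after fibroblast medium therefore stays open.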
